A study of Solanum lycopersicum with 24 samples.

How the data were processed

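RNA was sequenced from leaves of Moneymaker tomato in 24 libraries, 3 for each of 8 groups. The groups were assigned from the sample titles, which also carry the replicate numbers 1 to 3. CT stands for control, S for salt, HS for heat, S+HS for both stresses together, and Pp marks plants inoculated with Pseudomonas putida. The labels say that total RNA was isolated with a plant RNeasy kit and that libraries followed standard Illumina protocols. Strandedness, read length and any sequencing batch are not given in the sources used here.

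The deposited table held 1 normalized count, a signal that is never negative, for each of 34075 gene identifiers in each library. The submitters' processing notes name FastQC 0.11.7, STAR 2.4.0.1 and DESeq2 1.20.0. They name the build TAIR10, an Arabidopsis build, although the gene identifiers in the table have the tomato form beginning with Solyc. The annotation release and the read counter are not given in the sources used here. In the deposited table, 100% of the normalized counts were whole multiples of the library's smallest value above 0, within a tolerance of 1e-06 reads. Dividing by that smallest value therefore returned whole reads, and the library factors matched recomputed median-of-ratios size factors to a relative difference of 4.44e-15. In 2 libraries, HS replicate 3 and S+HS replicate 2, the factor lay so close to 1 that low values alone cannot tell the multiples from rounding. No gene length or per-million scaling was found in the values. Because size factors remove a common scale, a change in the total amount of RNA per leaf cannot be seen in these values.

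Total reads per library ran from 8371630 to 17978690, and 18855 to 21392 genes had at least 1 read. Another 8929 identifiers had no read in any library. Intervals and limits given for low counts cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing in the labels says that the 3 libraries of a group came from separate plants or pools of plants, although 8 plants per treatment and repeated experiments are described. The p-values therefore measure only the spread between these libraries, which may be technical.

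The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trended variance, for the 19140 genes with a mean of at least 10 normalized counts over the 24 libraries. All 8 groups entered 1 fit with 16 residual degrees of freedom, and 17 contrasts were taken from it. Within each contrast, p-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p at or under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. Interactions were contrasts of the same fit, such as the S+HS effect minus the S and HS effects.

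For the size of whole responses, the covariance of fold changes across genes was reduced by the part expected from the spread between replicates. The square root of the remaining variance is called the noise-corrected standard deviation, and correlations and slopes were formed from the same corrected values. Their ranges come from leaving out each library of the compared groups in turn. These values are across genes, and genes are not independent replicates. Overlaps of calls were set beside the overlap of independent lists and, where control libraries were shared, beside 20 simulations of groups with no effect. Independent lists take each tested gene as equally likely to be called. Abundant genes were called more often, which by itself raises overlaps in the same and in opposite directions. For pairs of inoculation effects, all 400 regroupings of the libraries within the 2 conditions were enumerated and the absolute covariance compared, two-sided. The 100 most abundant genes were those with the highest mean over all 24 libraries.

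Genes are given by identifier because the table does not pair identifiers with names. None of its identifiers (0 of 34075) occurs in the name table used here, which belongs to the assembly SLM_r2.1. For that reason 38 lists of genes by function, fixed before the data were examined, could not be filled, and neither the planned list tests nor marker checks for other cell types were run. By a rule fixed before the data were examined, the identifiers printed for a comparison are the 2 largest rises and 2 largest falls. They were taken among called genes whose higher group mean was at least 100 normalized counts and, for comparisons of 2 groups, whose libraries did not overlap. A fold against a group with no read is a bound, computed with a floor of 3 reads per library. That floor holds for independent reads only. Replicates spread more widely than counting alone, so folds printed as at least a value may be too high as bounds. Where the lower group held 1 to 3 reads, the ratio of pooled reads is given with an exact 95% counting interval. It is the summed reads of a group divided by the sum of its size factors, and it differs from the ratio of mean normalized counts.

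The procedure was tested on simulated libraries drawn from the real means and totals, with 200 genes changed. In the simulated S against CT comparison over 19121 genes, 22% of 50 genes changed 1.5-fold were called. The shares were 46% at 2-fold, 82% at 4-fold and 88% at 8-fold. In that comparison 7 unchanged genes were called, 33 in the simulated S+Pp against S comparison and 42 of all 43 calls in the simulated S+Pp against CT+Pp comparison. The share of unchanged genes with an unadjusted p under 0.05 ran from 1.43% for S+HS+Pp against S+HS to 11.1% for S+Pp against CT+Pp, so the shared estimate of spread was too liberal for some comparisons and too strict for others.

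The alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, no low-count filter, a minimum mean of 50 and TMM factors (edgeR 4.0.16) on top of the deposited scaling. The others were a replicate block, a fit of the compared groups alone, edgeR and DESeq2 1.42.0 on the recovered reads, and each replicate left out in turn. A minimum mean of 1000 for the noise-corrected values, and all alternatives for the slopes of the S+HS effect on the single effects, were chosen after seeing the data. The edgeR quasi-likelihood test on recovered reads called 3123 genes in S against CT, 5595 in HS against CT and 6903 in S+HS against CT. Figures were drawn with matplotlib from the computed values.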

Results

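Leaf transcriptomes of tomato plants under salt, heat and their combination were measured by RNA sequencing, with and without a root-associated bacterium. Seedlings of the cultivar Moneymaker were 3 weeks old when their roots received Pseudomonas putida KT2240, the strain name given in the labels, at an optical density of 0.05, or buffer. Stress began 10 days later. Salt plants were watered with 150 mM NaCl over 15 days, and heated plants spent 3 days at 37 °C, against greenhouse averages of 25.0 °C by day and 18.0 °C by night. The 8 groups (CT, S, HS, S+HS and the same with Pp) held 3 libraries each. Total reads lay between 8371630 in S+HS replicate 1 and 17978690 in HS replicate 2.

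Across tested genes, log2 values of libraries of the same group correlated with r from 0.876 to 0.954, and the highest r between libraries of different groups was 0.903. In CT+Pp the highest r within the group was 0.884 against 0.885 to a library of another group, and in S+Pp it was 0.900 against 0.903. The first principal component held 27.2% of the variance and parted the 12 heated libraries, with group means from 34.8 to 90.6, from the 12 unheated ones, with group means from -76.2 to -54.1. The second held 9.83% and parted the 12 salted libraries from the 12 unsalted ones. Its group means ran from -43.02 to -24.29 with salt and from 11.03 to 68.4 without. S+HS had a mean of -41.6 ± 0.743 (SD, n = 3) and HS a mean of 68.4 ± 0.355 (SD, n = 3). Among genes of 200 to 1000 normalized counts, the variance between replicates was 9.48 times the counting variance in CT and ranged from 6.09 times in S+HS to 12.9 times in S+Pp.

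**Figure D1:**
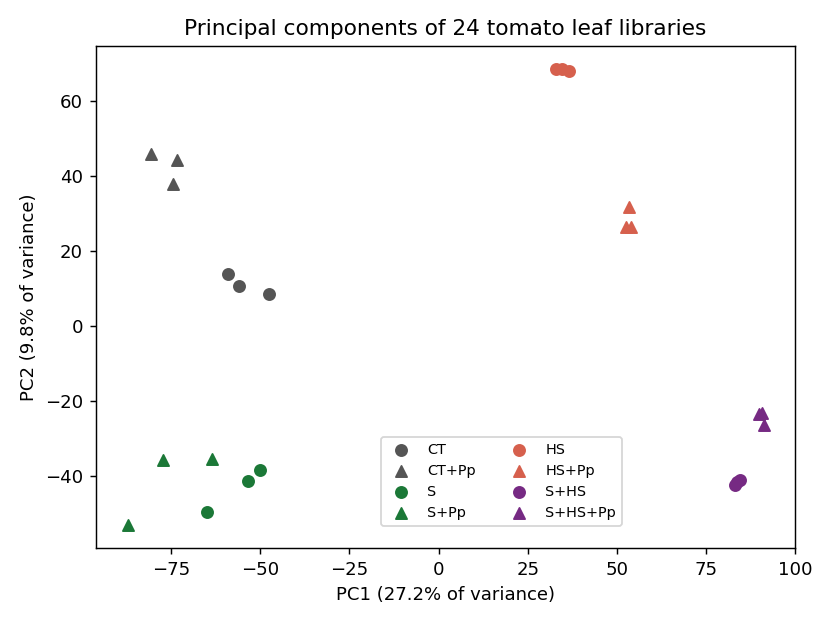
First principal component (horizontal, 27.2% of variance) against the second (vertical, 9.83%) for 24 leaf libraries, computed on log2(normalized count + 1) of the tested genes. Circles are uninoculated and triangles inoculated libraries, coloured by stress, and the heated groups lie to the right of 0 with group means from 34.8 to 90.6.

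**Figure D2:**
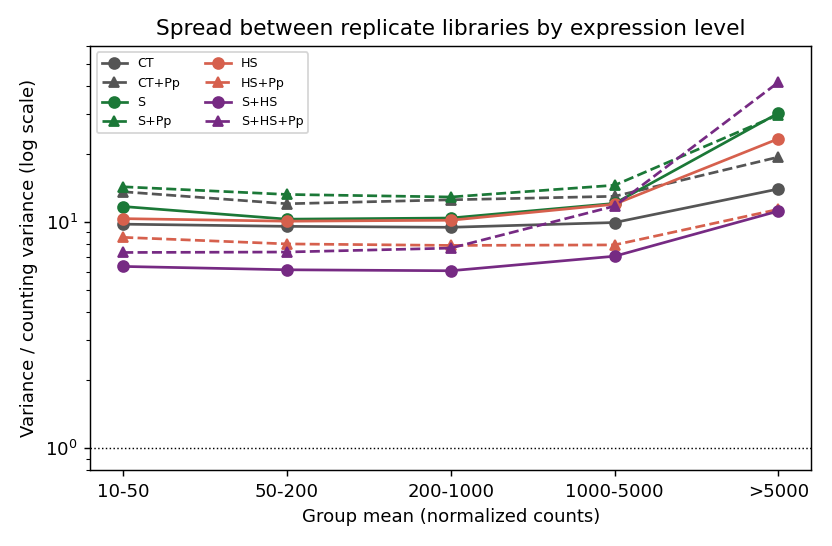
Variance between the 3 replicate libraries divided by the variance of read counting alone (vertical, log scale) for genes binned by group mean in normalized counts (horizontal). Each line is 1 group, dashed where inoculated, the dotted line marks a ratio of 1, and the CT line lies at 9.79 in the lowest bin and 14 in the highest.

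The comparison of S with CT addressed salt alone. Salt raised 1700 genes and lowered 1420 of 19140, and 678 of the raised and 443 of the lowered genes differed by at least 2-fold. The most abundant transcripts mostly rose: of the 100 most abundant genes 64 were called higher and 14 lower, with a median log2 fold change of 0.32. These 100 genes took 22.4% ± 0.345 (SD, n = 3) of normalized counts in S and 19.0% ± 0.211 (SD, n = 3) in CT. All 3 S libraries lay above all 3 CT libraries, which in an exact permutation test gives p = 0.1, the smallest that 3 against 3 allows. The largest rise was that of Solyc06g061200.1, from 1.52 ± 2.63 to 146 ± 31.1 normalized counts (SD, n = 3; limma log2 fold change 6.36, SE 1.09, adjusted p = 2.26e-05). Solyc01g103920.3 rose from 2.25 ± 3.89 to 114 ± 25.4 and stood at 1546 ± 96.1 in HS. Solyc11g069770.2 fell from 107 ± 42.4 to 0.794 ± 1.38 normalized counts, a CT to S ratio of pooled reads of 158 (exact 95% counting interval 43.4 to 1309) on 2 reads in S. Solyc04g009980.4 fell from 145 ± 25.9 to 2.41 ± 2.09 normalized counts. The noise-corrected standard deviation of the salt effect across genes was 0.65 on the log2 scale (0.64 to 0.66 with any library left out).

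Heat alone changed more genes than salt alone. HS raised 2677 genes and lowered 2918, of which 1151 and 1177 differed by at least 2-fold, and the noise-corrected standard deviation was 0.93 (0.92 to 0.94). The direction among abundant transcripts was opposite to that under salt. Of the 100 most abundant genes 23 rose and 64 fell (median log2 fold change -0.33), and their share of normalized counts was 17.4% ± 0.119 (SD, n = 3). Solyc03g082420.3 rose from 18.1 ± 20.3 to 13048 ± 282 normalized counts (SD, n = 3; limma log2 fold change 10.57, SE 0.92, adjusted p = 3.13e-12), and it stood at 4.77 ± 8.25 in S. Solyc03g113930.3 rose from 1 read in the CT libraries to 1526 ± 135 normalized counts, a ratio of pooled reads of 4996 with an exact 95% counting interval of 896 to 197358. Solyc05g054750.3 fell from 271 ± 15.9 normalized counts to 0 reads in all 3 HS libraries, which was at least 111-fold lower. Solyc05g005870.3 fell from 162 ± 50.5 to 0 reads and was at least 66.8-fold lower. In all, 7 genes without a read in CT reached a mean of at least 50 normalized counts in HS, against 1 such gene in S.

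The response to S+HS was the largest of the 3 by number of calls and by spread. S+HS raised 3351 genes and lowered 3619, of which 1863 and 1565 differed by at least 2-fold, and the noise-corrected standard deviation was 1.17 (1.16 to 1.18). Abundant transcripts fell further than in HS. Of the 100 most abundant genes 25 rose and 69 fell against CT (median log2 fold change -0.60), while against HS 18 rose and 59 fell, and their share was 15.3% ± 0.122 (SD, n = 3). The S+HS libraries held 21135 ± 145 genes with a read (SD, n = 3) and a variance ratio of 6.09, against 20247 ± 401 and 9.48 in CT. Solyc01g102960.3 rose from 6.06 ± 10.5 to 9351 ± 618 normalized counts (SD, n = 3; limma log2 fold change 11.77, SE 0.72, adjusted p = 4.79e-17), with 1965 ± 62.7 in HS. Solyc01g081250.3 rose from 2.57 ± 4.45 to 7004 ± 354, with 347 ± 28.1 in HS. Solyc05g054750.3 fell from 271 ± 15.9 to 0.807 ± 1.40, a CT to S+HS ratio of pooled reads of 397 (exact 95% counting interval 110 to 3286) on 2 reads. Solyc06g062460.3 fell from 475 ± 38.1 to 2.91 ± 3.01, with 49.9 ± 6.46 in HS. There were 20 genes without a read in CT that reached a mean of at least 50 in S+HS, with bounds from at least 20.1-fold to at least 342-fold.

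**Figure D3:**
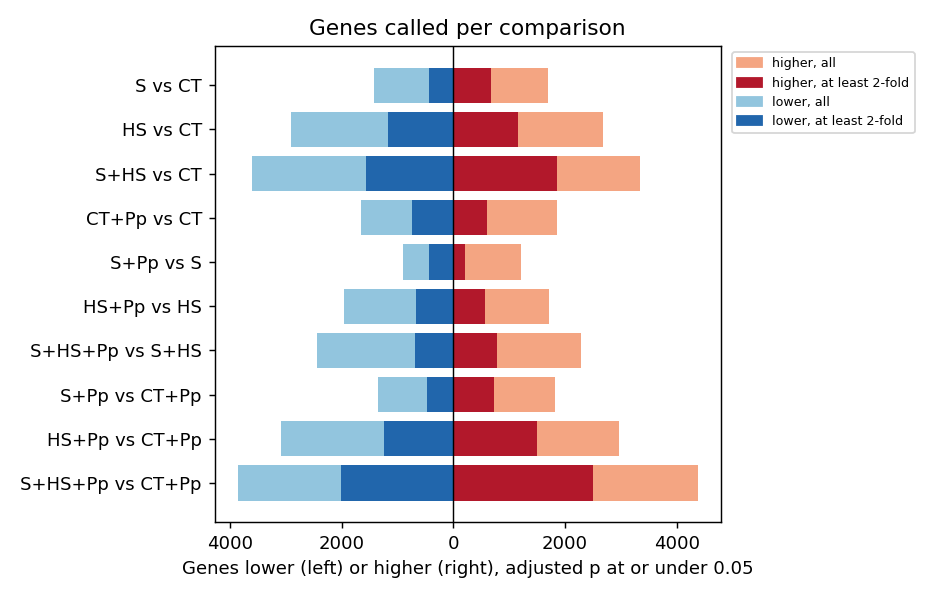
Number of genes called at an adjusted p at or under 0.05 in 10 comparisons, with lower genes to the left of 0 and higher genes to the right. Dark parts are genes that differed by at least 2-fold, and the longest bars belong to S+HS+Pp against CT+Pp with 4377 higher and 3869 lower genes.

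The combination was then compared with each single stress. Against HS, salt added to heat raised 2656 and lowered 2997 genes, and against S, heat added to salt raised 3274 and lowered 3465. Some genes stood apart in the combination: 1110 were higher in S+HS than in each of CT, S and HS, and 1428 were lower than in each, of which 453 and 435 did so by at least 2-fold in all 3 comparisons. The salt-by-heat interaction, which tests the departure of the S+HS effect from the summed single effects on the log2 scale, was called in 3900 genes (1743 above and 2157 below the sum). Solyc03g116390.4 had no read in CT, 45.3 ± 15.4 normalized counts in S, 247 ± 12 in HS and 4.83 ± 1.61 in S+HS (limma interaction log2 estimate -10.93, SE 0.71, adjusted p = 7.67e-16). Solyc12g098900.2 was likewise higher in S (527 ± 38.3) and HS (419 ± 33.9) than in CT (19.2 ± 16.9) and S+HS (29.9 ± 12.9). Solyc12g009240.1 had 8.21 ± 3.39 in CT, 1.99 ± 3.44 in S, 0 reads in HS and 236 ± 22.2 in S+HS. Solyc03g098790.3 had 44.8 ± 22.1 in CT, 0 reads in S, 782 ± 79.9 in HS and 5439 ± 274 in S+HS.

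Genes that both single stresses moved the same way mostly changed less in S+HS than the sum. Of the 639 genes raised by both S and HS, 441 were also raised in S+HS, 408 had an interaction below the sum and 33 above it. Of the genes lowered by both, 375 were also lowered in S+HS, 241 fell by less than the sum and 26 by more. Another 604 genes were moved in opposite directions by S and HS, of which 296 followed the HS direction in S+HS, 169 followed S and 139 were not called. These classes were selected on libraries that also enter the interaction, which by itself favours departures below the sum. The noise-corrected slope of the S+HS effect on the summed effects was 0.595 (0.585 to 0.606 with any library left out). The correction removes the part due to spread between libraries, but not a deviation common to all libraries of a group. The noise-corrected correlation with the sum was 0.639, and the standard deviations were 1.255 for the sum and 1.17 for S+HS. A slope below 1 is therefore not a uniform reduction of the summed effects. Fitted jointly, the slope on the HS effect was 0.696 (0.689 to 0.706) and that on the S effect 0.414 (0.388 to 0.436). Among genes with a mean of at least 1000, the slope on the summed effects was 0.732. There the slope on the S effect was 0.165 and that on the HS effect 0.915.

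The 3 stress responses overlapped. S and HS shared 1117 genes called in the same direction, 639 of them raised, where independent lists would share 454 and 238. S and S+HS shared 860 raised and 757 lowered genes (298 and 268 for independent lists), and HS and S+HS shared 1411 and 1703 (469 and 552). Calls in opposite directions numbered 604 for S and HS (458 for independent lists), 512 for S and S+HS (570) and 569 for HS and S+HS (1017). Simulated groups without an effect shared at most 0.05 genes on average, but such groups give almost no calls, so this does not measure what the shared CT libraries add to lists of real effects. Across genes the correlation of fold changes was 0.312 for S and HS, 0.379 for S and S+HS and 0.597 for HS and S+HS, and simulated groups without an effect, which share the CT libraries, gave 0.50. The covariances were 0.290, 0.419 and 0.808 against a simulated 0.157, 0.156 and 0.157. The 3 CT libraries cannot be divided into sets of at least 2, so part of the excess may come from the shared controls. After noise correction, which takes the shared libraries into account, the correlations were 0.242, 0.363 and 0.609, and that of S and S+HS was 0.202 among genes with a mean of at least 1000.

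The next comparisons addressed what inoculation with P. putida changed in each condition. In unstressed leaves CT+Pp had 1848 genes higher and 1659 lower than CT, of which 600 and 736 differed by at least 2-fold. Abundant transcripts rose: 79 of the 100 most abundant genes were higher and 4 lower, and their share was 22.5% ± 0.166 (SD, n = 3) against 19.0% ± 0.211 in CT. The CT+Pp libraries also held fewer genes with a read (19209 ± 246 against 20247 ± 401 in CT; SD, n = 3) and a higher ratio of replicate to counting variance (12.5 against 9.48). Solyc03g116390.4 rose from 0 reads to 124 ± 49.2 normalized counts (SD, n = 3; at least 45.6-fold higher; limma adjusted p = 4.85e-14), and Solyc06g072130.4 rose from 0 reads to 104 ± 39.5 (at least 38.1-fold higher). Solyc09g008840.4 fell from 120 ± 47.6 to 4.15 ± 7.18, and Solyc01g079180.4 fell from 114 ± 12 to 4.53 ± 7.85. With only the CT and CT+Pp libraries in the fit, 2264 genes were called, 1283 higher and 981 lower.

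Under salt the inoculation effect was the smallest of the 4, with a noise-corrected standard deviation of 0.46 (0.44 to 0.49) against 0.65 (0.64 to 0.66) in unstressed leaves. S+Pp had 1217 genes higher and 897 lower than S, of which 205 and 437 differed by at least 2-fold. Again 76 of the 100 most abundant genes rose and 7 fell, and their share reached 24.6% ± 0.347 (SD, n = 3). The genes with a read numbered 19357 ± 543 in S+Pp and 19944 ± 520 in S (SD, n = 3), and the variance ratios were 12.9 and 10.4. Solyc01g081250.3 rose from 0.794 ± 1.38 to 198 ± 50.9 normalized counts (SD, n = 3), a ratio of pooled reads of 289 with an exact 95% counting interval of 79.8 to 2396 on 2 reads in S. Solyc11g011330.2 fell from 109 ± 32.0 to 5.24 ± 9.08, and Solyc09g007010.1 fell from 141 ± 46 to 11.7 ± 13.7 (limma adjusted p = 1.54e-04). The other rise that met the rule, of Solyc05g007940.3 from 31.2 ± 27.5 to 108 ± 43.3, was not called without S replicate 1 (limma adjusted p = 0.39) or by edgeR (adjusted p = 0.154), and its adjusted p ran from 0.00505 to 0.39 over 14 alternatives. With only the S and S+Pp libraries in the fit, 989 genes were called, 699 higher and 290 lower, and Solyc09g007010.1 was not among them (adjusted p = 0.0603, the highest of 15 alternatives, the lowest being 1.88e-09).

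Under heat the abundant transcripts moved the other way on inoculation. HS+Pp had 1716 genes higher and 1970 lower than HS, and 15 of the 100 most abundant genes rose while 49 fell. Their share was 16.8% ± 0.0937 in HS+Pp and 17.4% ± 0.119 in HS (SD, n = 3), with 20525 ± 279 and 20574 ± 137 genes with a read and variance ratios of 7.88 and 10.2. In the test of the difference from the effect in unstressed leaves, 76 of the 100 genes were called lower and 4 higher. Solyc03g026280.3 rose from 9.99 ± 9.13 to 169 ± 56.1 normalized counts (SD, n = 3; limma log2 fold change 4.71, SE 0.62, adjusted p = 1.38e-07). Solyc09g074500.3 rose from 10.6 ± 1.10 to 221 ± 27.6 and had no read in the 4 unheated groups. Solyc03g098720.3 fell from 181 ± 26.9 to 0 reads and was at least 57.6-fold lower, and Solyc10g076670.3 fell from 107 ± 15.6 to 0 reads and was at least 34.3-fold lower.

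The inoculation effect under S+HS was the largest of the 4 in number of calls. S+HS+Pp had 2284 genes higher and 2440 lower than S+HS, and the noise-corrected standard deviation was 0.74 (0.73 to 0.75). Of the 100 most abundant genes 11 rose and 77 fell, and their share dropped to 12.8% ± 0.437 (SD, n = 3), with 21167 ± 296 genes with a read and a variance ratio of 7.67. Solyc01g081250.3, raised by S+HS and by inoculation under salt, fell from 7004 ± 354 to 2.11 ± 3.65 normalized counts (SD, n = 3; limma log2 fold change -11.82, SE 0.72, adjusted p = 2.30e-16), while it stood at 1786 ± 189 in HS+Pp. Solyc01g044365.1 fell from 105 ± 2.16 to 1.5 ± 2.61. Solyc02g086310.2 rose from 0 reads to 680 ± 11.8 (at least 218-fold higher; limma adjusted p = 1.78e-05, DESeq2 adjusted p = 0.124, with a range over 15 alternatives from 2.28e-11 to 0.124), and Solyc01g096720.4 rose from 0 reads to 284 ± 15.4 (at least 91.1-fold higher).

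**Figure D4:**
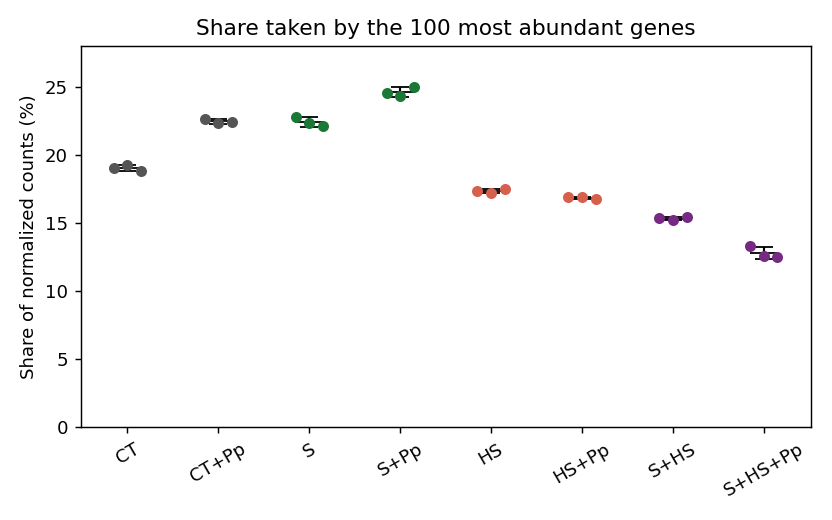
Share of normalized counts taken by the 100 genes with the highest mean over all 24 libraries (vertical, percent) in each group (horizontal). Points are libraries, and bars mark the mean and SD of 3 libraries, which run from 24.6% ± 0.347 in S+Pp to 12.8% ± 0.437 in S+HS+Pp.

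Few genes were called for inoculation in the same direction in every condition. A missing call does not show a missing effect: in the simulated S against CT comparison, 46% of genes changed 2-fold were called. Of 8269 genes called in at least 1 of the 4 conditions, 4501 were called in exactly 1, and 2504 were called in opposite directions in different conditions. In all, 40 genes were raised and 16 lowered in each of the 4, where independent lists would give 1.26 and 1.02. The mean effect over the 4 conditions was called in 3193 genes (1648 higher, 1545 lower), and 523 of the higher and 555 of the lower genes had the same direction in each condition. The genes with the mean effects largest in size were each called in only some of the conditions. Solyc03g116390.4 had the largest mean rise (log2 3.15): it rose without stress and from 4.83 ± 1.61 to 421 ± 18.5 normalized counts under S+HS (SD, n = 3). It was not called under salt (45.3 ± 15.4 to 33.5 ± 9.21; limma adjusted p = 0.691) or heat (247 ± 12 to 230 ± 33.5; limma adjusted p = 0.925). Solyc10g078770.2 followed (log2 3.08), rising from 6.57 ± 5.74 in CT to 468 ± 109 in CT+Pp and from 25.6 ± 7.33 to 604 ± 85.9 under S+HS. It was not called under salt (107 ± 46.9 to 261 ± 22; limma adjusted p = 0.0692) or heat (293 ± 98.2 to 259 ± 42.9; limma adjusted p = 0.903). Of the largest mean falls, Solyc01g079180.4 (log2 -2.71) was called lower in unstressed leaves, and Solyc09g089530.3 (log2 -2.26) under heat (limma adjusted p = 0.0249), and neither was called in another condition. The called fall of Solyc09g089530.3 was from 33.9 ± 26.4 to 2.27 ± 3.93 normalized counts (SD, n = 3). Under S+HS this gene also went down, from 377 ± 25.7 to 136 ± 34.5, without a call.

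The effects of inoculation in unstressed and salt-treated leaves resembled each other, and those under S+HS were opposed to those under either single stress. The noise-corrected correlation across genes was 0.524 (0.483 to 0.549 with any library left out) between CT and S, and -0.310 (-0.322 to -0.294) between HS and S+HS. It was -0.322 (-0.340 to -0.306) between S and S+HS, or -0.532 among genes with a mean of at least 1000, 0.278 between S and HS, 0.138 between CT and HS and 0.0872 between CT and S+HS. Uncorrected correlations were weaker, at 0.207 between CT and S, -0.212 between HS and S+HS and -0.156 between S and S+HS. They were 0.122 between S and HS, 0.0772 between CT and HS and 0.0535 between CT and S+HS. For each of these 6 pairs the covariance exceeded that of every other regrouping of the libraries, which in an exact permutation test gives p = 0.01, the smallest that 400 regroupings allow, and a Benjamini-Hochberg adjusted p of 0.01. Regrouping also removes the inoculation effects themselves, so this p cannot separate a relation between effects from their mere presence. All 6 pairs reached it, CT and S+HS with a correlation of 0.0872 included, so it is no evidence of resemblance or opposition. Between HS and S+HS 1518 genes were called in opposite directions, where independent lists would give 454. The tests of the difference between the inoculation effect in stressed and unstressed leaves called 1390 genes for salt, 3249 for heat and 4131 for both. With only the 4 groups concerned in the fit, 877 genes were called for salt.

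The stress responses of inoculated plants were compared with those of uninoculated plants, which share no library. Against CT+Pp, S+Pp raised 1821 and lowered 1360 genes, HS+Pp raised 2970 and lowered 3095, and S+HS+Pp raised 4377 and lowered 3869. With only the S+Pp and CT+Pp libraries in the fit, 1373 genes were called (915 higher, 458 lower). Salt responses shared 783 raised and 421 lowered genes (162 and 100.9 for independent lists), heat responses 1021 and 1535 (415 and 472), and S+HS responses 1844 and 2232 (766 and 732). The noise-corrected correlations were 0.548, 0.594 and 0.702. The spread of the response was smaller in inoculated plants under salt, at 0.831 times that of uninoculated plants (0.812 to 0.854 with any library left out). Under heat the ratio was 1.05 (1.04 to 1.06) and under S+HS 1.08 (1.07 to 1.09), but over other pseudocounts, filters and scaling it ran from 0.975 to 1.07 and from 1.00 to 1.10, so the heat ratio did not keep to one side of 1. Among stressed plants, the inoculation effect was set against the uninoculated stress response. The noise-corrected slope was -0.159 (-0.165 to -0.153) under S+HS and -0.0739 (-0.0914 to -0.0622) under heat. Under salt the slope was -0.00458, with a range from -0.0253 to 0.0288 that includes 0, and over other settings it ran from -0.0158 to 0.0972. Without the correction the slopes were -0.191 under S+HS, -0.170 under heat and -0.265 under salt. The stressed uninoculated libraries enter both sides of each slope with opposite sign. A deviation common to these libraries would therefore give a negative slope, since the correction removes only the spread between libraries. A reversal of the stress response by inoculation cannot be read from the slopes alone.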

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

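The tests on the orientation of opposite calls, on abundant genes alone, on same-numbered libraries and on a constant coefficient of variation were chosen after the results were seen.

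Tests of the difference itself marked 4 effects as unequal between conditions. The effect of heat differed between salt-treated and unsalted leaves in 3900 genes. The effect of inoculation differed from that in unstressed leaves in 1390 genes under salt, in 3249 under heat and in 4131 under both. Of the 1390 genes with a called difference under salt, 140 were called in opposite directions under salt and in unstressed leaves. These numbered 586 of 3249 under heat and 799 of 4131 under both. A gene without a call in a condition has no established direction there, so these counts do not give the share of opposite effects. Over all tested genes, the effect under salt was set beside that in unstressed leaves. There were 594 genes raised in both, 303 lowered in both and 140 called in opposite directions (118, 77.7 and 192 for independent lists). Under heat these were 453, 350 and 586 (166, 171 and 339), and under both stresses 483, 371 and 799 (221, 211 and 434).

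The opposed effects of inoculation under S+HS and under single stresses are a pattern to follow up, tested here for HS and S+HS. A wrong factor per library would shift all genes one way and pile the opposite calls into 1 orientation. With TMM factors 776 genes were higher under HS and lower under S+HS, and 744 the reverse. That was at least 3.32 times the number for independent lists in each orientation. Independent lists ignore that abundant genes were called more often, which raises overlaps in any direction. For this pair, calls in the same direction under the deposited scaling numbered 178 raised and 298 lowered (205 and 251 for independent lists). The correlation was -0.322 among 2198 genes with a mean of at least 1000, so it was also negative in that set. A correlation ignores a shift common to all genes of a set. The 100 most abundant genes mostly fell on inoculation in both conditions. Under HS 15 were higher and 49 lower, and under S+HS 11 and 77. The correlation of -0.322 is not a test of noise of low counts. The inoculation effects under HS and S+HS share no library, so independent noise has no expected covariance between them at any abundance. The correlation under TMM factors (-0.310) and that of same-numbered libraries (-0.000832) do not bear on the cause, since a common factor hardly moves a correlation across genes and a batch that follows the numbers is balanced over groups. A batch or plant pool that differed between whole groups cannot be told apart from the treatments, so a biological difference and such a batch both stay open.

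The variance between replicates grew in proportion to the mean at nearly every level, a second pattern. Spread between plants with 1 coefficient of variation at each level would keep the dispersion of abundant genes. Above 5000 normalized counts the dispersion was at most 0.0774 of that at 50 to 200, which restates the pattern and is not separate evidence. Several reads counted per sampled molecule may account for the pattern: where the other libraries of a group averaged 8 to 12 reads, the remaining one had no read in 31.7% of 18483 cases, against 0.0375% for independent reads. Simulated clumps of the measured size gave 37.9%, and a negative binomial of the same variance gave 11%. Whether amplification, little input or the read counting produced such clumps was not tested, nor whether the clumps bear on the share of the 100 most abundant genes.

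Counts from random regroupings of the libraries were set beside the real counts. For comparisons of 3 libraries with 3, 1 of 10 splits (the real one) gave as many genes in each of the 12 comparisons, too few splits for a share under 0.05. The real counts ran from 2114 for S+Pp against S, where the highest other split gave 8, to 8246 for S+HS+Pp against CT+Pp, where it gave 0. The highest of the other splits over these comparisons was 31, for S+Pp against CT+Pp, whose real count was 3181. In the rest the highest other split gave from 0 to 4 genes. For the contrasts of 4 or 8 groups, 100 splits were used. The salt-by-heat interaction gave 3900 against a highest other of 2428, and the mean inoculation effect 3193 against 1300. The inoculation effect under both stresses against that in unstressed leaves gave 4131 against 3686. In each of these, 1 of 100 splits, the real one, was as large. For the same difference under salt (1390) and heat (3249), 2 of 100 splits were as large, the real one included. The highest other gave 3101 and 3962 there. Splits with counts this high mix libraries of groups that differ, so they do not show what an absent effect would give. The shares under 0.05 therefore do not exclude chance for these contrasts.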

How the results depend on the processing

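For the 17 counts of called genes, the number stayed within 1.5 times under pseudocounts of 0.5 and 5, both other filters, TMM factors, edgeR (0.944 to 1.03 times) and DESeq2 (1.03 to 1.40 times). With only the compared groups in the fit, 13 of 17 stayed within 1.5 times. The others were 2264 for CT+Pp against CT, 989 for S+Pp against S (699 higher, 290 lower), 1373 for S+Pp against CT+Pp and 877 for the salt difference of inoculation effects. The same setting raised other counts, by at most 1.35 times (from 4724 to 6375 for S+HS+Pp against S+HS), and the mean inoculation effect uses all groups in either fit. In the simulation, the 8 comparisons where over 5% of unchanged genes had an unadjusted p under 0.05 were the 8 whose counts fell, and the 8 whose counts rose were all below 5%. A shared spread too small for some groups and too large for others would give this split, and the fewer residual degrees of freedom of the smaller fits were not tested apart. Leaving out each replicate moved no count by over 1.5 times, as for S against CT (2470 to 2771) and S+Pp against S (1614 to 2133). For the 36 pairs of gene and comparison, 616 of 625 values kept direction and threshold, 9 lost the threshold and 0 reversed. Those 9 concern Solyc05g007940.3, Solyc09g007010.1 and Solyc02g086310.2. Overlaps of genes changed at least 2-fold were 346 for S and HS (68.0 for independent lists), 550 for S and S+HS (102) and 1103 for HS and S+HS (208). Of 192 alternative noise-corrected values, 133 moved by more than a leave-one-out error and 0 beyond it changed sign. The salt slope along the stress response, whose range includes 0, went from -0.00458 to 0.0972. The error was averaged over omissions of all 24 libraries, and libraries outside a comparison leave its value unchanged. It is therefore too small, and the count of 133 depends on it. The leave-one-out ranges still understate how far the values depend on the settings. Standard deviations moved to between 0.762 and 1.2 times the reported value, lowest mostly at pseudocount 5 and highest mostly at 0.5. The minimum mean of 1000, chosen after seeing the data, moved most correlations furthest: CT and S inoculation effects from 0.524 to 0.356, S and S+HS inoculation effects from -0.322 to -0.532, and S and S+HS responses from 0.363 to 0.202. The slope of the S+HS effect on the S effect was 0.398 to 0.450 otherwise and 0.165 there. The slope on the summed effects was 0.589 to 0.604 otherwise and 0.732 there. Replicate numbers did not pair the libraries: same-numbered deviations correlated with a mean r of -0.000832 and at most 0.0443, and 6 of 24 libraries were closest to their own number. With the number as a block, 3122 genes were called for S against CT, 5597 for HS against CT and 6945 for S+HS against CT, and over the 17 counts the ratio was 0.984 to 1.00. Other settings for the gene list tests were not run, because no list could be filled. Low genes were measured less precisely: the median coefficient of variation in CT was 49.3% at 10 to 50 normalized counts and 3.07% above 5000. The variance in that lowest class was 9.79 times the counting variance, and how much depth contributes was not tested.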

Other observations

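The tests in this part were chosen after the results were seen. The digits after Solyc give the chromosome, and identifiers are numbered along it, so neighbours can be read from the identifiers of the tested genes. The longest runs of neighbouring genes called in the same direction fell in 2 regions, named after their values were seen. Each region is the longest run in S+HS against CT on its chromosome, so its calls in that comparison were fixed by the choice. On chromosome 2, the 11 tested identifiers from Solyc02g070910.3 to Solyc02g071030.2 summed to 116902 ± 5065 normalized counts in CT (SD, n = 3), 217606 ± 2212 in S, 100357 ± 2707 in HS and 42518 ± 299 in S+HS. With inoculation the sums were 198568 ± 5724 in CT+Pp, 265707 ± 9074 in S+Pp, 56122 ± 75.3 in HS+Pp and 42921 ± 5971 in S+HS+Pp. All 11 were called lower in S+HS than in CT, by the choice of the region, and 9 were called higher and 1 lower in S. On chromosome 9, the 12 tested identifiers from Solyc09g083435.1 to Solyc09g089540.4 summed to 1034 ± 89.7 normalized counts in CT, 930 ± 200.3 in S, 11381 ± 528 in HS and 55428 ± 2324 in S+HS, and all 12 rose in S+HS. With inoculation the sums were 1698 ± 134 in CT+Pp, 1117 ± 255 in S+Pp, 4344 ± 105 in HS+Pp and 28307 ± 1969 in S+HS+Pp. Values of single identifiers in such runs are uncertain if near-identical copies share reads, and the sums over a run are less exposed to that.

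Called genes lay next to genes called in the same direction more often than in 1000 shuffles of the order along chromosomes. For S against CT there were 389 such pairs against 257 ± 14.8 (SD over shuffles), for HS against CT 1034 against 821 ± 24.2, and for S+HS against CT 1602 against 1271 ± 29.3. For inoculation there were 468 pairs against 323 ± 17 in unstressed leaves and 787 against 583 ± 20.9 under S+HS. In the 7 comparisons examined the permutation p was 0.001, the smallest that 1000 shuffles allow. At a distance of 10 identifiers the count was at the shuffled level, with 256 for S against CT and 1269 for S+HS against CT. The longest run was 12 genes against 10 in shuffled orders for S+HS against CT, and 9 against 6 for S against CT. It was 11 against 7 for HS+Pp against HS and 8 against 7 for CT+Pp against CT. Elsewhere it was shorter than in shuffled orders: HS against CT (6 against 9), S+Pp against S (4 against 6) and S+HS+Pp against S+HS (6 against 9).

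The share of counts in the 100 most abundant genes was 15.6% ± 1.85 in the 12 heated libraries and 22.1% ± 2.11 in the 12 unheated ones (SD, n = 12; two-sided permutation test p = 1e-05, the smallest that 100000 resamples allow). The 12 libraries of each kind come from 4 groups, so they are not 12 independent samples of heat. Under TMM factors the same class had 64 higher and 14 lower genes in S against CT, 23 and 64 in HS, and 25 and 69 in S+HS. The number of genes with at least 1 read (SD, n = 3) was 20247 ± 401 in CT, 19209 ± 246 in CT+Pp, 19944 ± 520 in S, 19357 ± 543 in S+Pp, 20574 ± 137 in HS, 20525 ± 279 in HS+Pp, 21135 ± 145 in S+HS and 21167 ± 296 in S+HS+Pp. CT+Pp and S had nearly equal shares (22.5% and 22.4%). Their libraries overlapped in genes with a read (19486 in CT+Pp replicate 3, 19415 in S replicate 1), and the difference between their means was not tested. Total reads divided by the ratio of replicate to counting variance at 200 to 1000 normalized counts gave, in the same order, 1243545, 816085, 1048741, 909928, 1316624, 1206862, 1622442 and 1494281. HS+Pp and S+HS+Pp had both a lower share and a lower such value than HS and S+HS, whereas CT+Pp and S+Pp had a higher share and a lower value than CT and S. Whether the share follows from the treatment or from how many molecules a library sampled was not tested.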
